A study of Mus musculus with 6 samples.

How the data were processed

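RNA was taken from primary mouse proximal tubular epithelial cells after 20 µM erastin2 for 24 h, 3 libraries labelled Atg5F/F and 3 labelled Atg5KO, all with the same batch date. Libraries were made with a stranded mRNA kit from Illumina, per the labels' protocols. Reads went through bcl2fastq, Trimmomatic 0.35, HISAT2 2.1.0, featureCounts 1.4.6 and edgeR, on the builds GRCm38 and mm10, per the submitters' processing notes. The annotation, the strand setting, the use of multi-mapping reads and the filters are not given in the sources used here.

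The authors deposited a single table of 24421 gene symbols with an FPKM value per library (fragments per kilobase of gene, scaled to library size). The authors' deposited table also gives a log2 fold change of Atg5KO over Atg5F/F, a p-value, an FDR and a score that ranks the rows. The authors' column named as an adjusted p-value behaved as an unadjusted p-value: its Benjamini-Hochberg adjustment over all rows met the FDR column within 4.7e-07. Symbols that spreadsheet software had turned into dates (27) and repeated symbols (2) were kept as rows. No mitochondrially encoded gene was analysed here.

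FPKM steps at low values gave back the reads. With a single length per gene and a single total per library, all 18296 genes above 0 (100%) came out as whole reads in every library, within a relative tolerance of 1.5e-09 or 2.0e-04 reads. The implied totals were 15528454 to 30004933 reads, of which the recovered genes held 99.6%, so the authors' FPKM carried no scaling beyond the library total. In simulated data the same steps recovered 98.9% of 2197 genes with a mean of at least 10 reads and the exact total of 6 of 6 libraries. The 10 most abundant genes held 5.6% to 6.5% of the FPKM sum of a library. Chi-square statistics of reads per degree of freedom were 3.3 to 6.8 between libraries of the same group, above the 1 that sampling noise gives, so no library was taken as a duplicate.

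The main test followed a plan fixed before the data were examined: limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend) on log2(FPKM + 1) of the 11559 genes with at least 1 FPKM in at least 3 of the 6 libraries, KO-labelled minus F/F-labelled, with Benjamini-Hochberg adjustment and calls at adjusted p under 0.05. Gene lists were also fixed beforehand (45, of which 43 had at least 3 tested members), with the KEGG oxidative phosphorylation list and the respiratory chain list as unions. Members were written from general knowledge of each pathway, without a pathway database. They were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over 45 lists. Camera with an estimated correlation and fry stood beside it; fry tests whether the genes of a list move on balance one way and does not compare the list with other genes. Named genes were Atg5, the 12 largest increases and 12 largest decreases among called genes whose groups did not overlap and whose higher mean reached 5 FPKM (leaving out predicted genes, Rik clones and pseudogenes), and from each list up to 4 called members with the largest absolute change, or 2 with the smallest p where none was called. Not every gene that met these rules is named in the text. Replicate numbers were checked for pairing and do not mark a shared animal in the labels.

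Alternatives planned beforehand were a replicate block, leaving out each library, median-ratio scaling, quantile normalization, a pseudocount of 0.1, no filter, a filter of 5 FPKM, robust eBayes, no variance trend, other thresholds and other list tests. Added after seeing the data were voom on the recovered reads, and removing each library's loess trend (span 0.5) on gene length, alone or with transcript GC content. GC was matched for 96.3% of the tested genes. Gene lengths were those implied by the FPKM values, and coordinates are from GENCODE vM21 on GRCm38. The list tests were run with the same variance settings throughout, so robust eBayes and the fit without a variance trend were not applied to them. Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 read the tables.

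The gene test was run on 10 simulations of reads with the real totals and lengths (11450 genes per simulation on average). Their spread was the real one averaged over genes of similar level. Pooled, it recovered 32.2% of genes changed 1.2-fold, 77.0% at 1.5-fold, 94.3% at 2-fold and 100% at 4-fold, and called 91 of 112525 unchanged genes. The pooled changed genes numbered only 491 to 500 per fold. Each simulation thus changed far fewer genes than were called in the real data, so these rates do not carry over to the real test. In 20 simulations with the respiratory chain list lowered by 0.18 and genes otherwise independent, camera called it in 20 with the preset and in 20 with the estimated correlation, and called 4 of 740 unchanged lists with the preset. Real genes are correlated, so the simulated rates of list calls are best cases.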

Results

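Messenger RNA was sequenced from primary mouse proximal tubular epithelial cells, the cells that line the first segment of the kidney tubule and reabsorb most of the filtrate. The cells of all 6 libraries had received 20 µM erastin2 for 24 h. Erastin2 is an analogue of erastin that blocks cystine uptake through system xc-, which starves the cell of glutathione and can lead to ferroptosis, a death driven by iron and lipid peroxidation. The libraries fell into 2 groups of 3, labelled Atg5F/F (floxed control) and Atg5KO. ATG5 is part of the conjugation machinery that attaches LC3 to the growing autophagosome. There was no untreated group, so each difference below is between genotypes under erastin2. A difference present without the drug cannot be told apart from a response to it that depends on genotype. The labels give no animal or culture for each replicate, so p-values measure only the spread between these samples, which may be technical. The deposited values were FPKM. The read totals they imply were 30004933, 15528454 and 22332418 for Atg5F/F replicates 1 to 3, and 19724355, 16922491 and 17402904 for Atg5KO replicates 1 to 3. Pearson correlations of log2 values ran from 0.994 to 0.997 within groups and from 0.978 to 0.984 between them, and the first principal component, with 70.9% of the variance, separated the groups.

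Atg5, the targeted gene (chromosome 10, 44268358 to 44364291 in GRCm38), was not lower in the libraries labelled Atg5KO. It was higher there. The FPKM values were 8.76, 8.95 and 7.94 in Atg5F/F replicates 1 to 3 and 13.3, 11.5 and 12.7 in Atg5KO replicates 1 to 3, resting on 618, 327 and 417 reads against 618, 457 and 520. The means were 8.55 ± 0.54 and 12.5 ± 0.94 FPKM (SD, n = 3), a log2 fold change of 0.50 (SE 0.066, limma adjusted p = 5.5e-04). An exact permutation test of the 6 values gave a two-sided p of 0.1, the smallest that 3 against 3 can give. A value for the whole gene cannot show whether an exon is missing, and the labels do not say which part of Atg5 was deleted, so the level neither supports nor contradicts the deletion. Because the labels could not be checked from this gene, the groups are named below as F/F-labelled and KO-labelled libraries, and every direction rests on those labels.

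**Figure D1:**
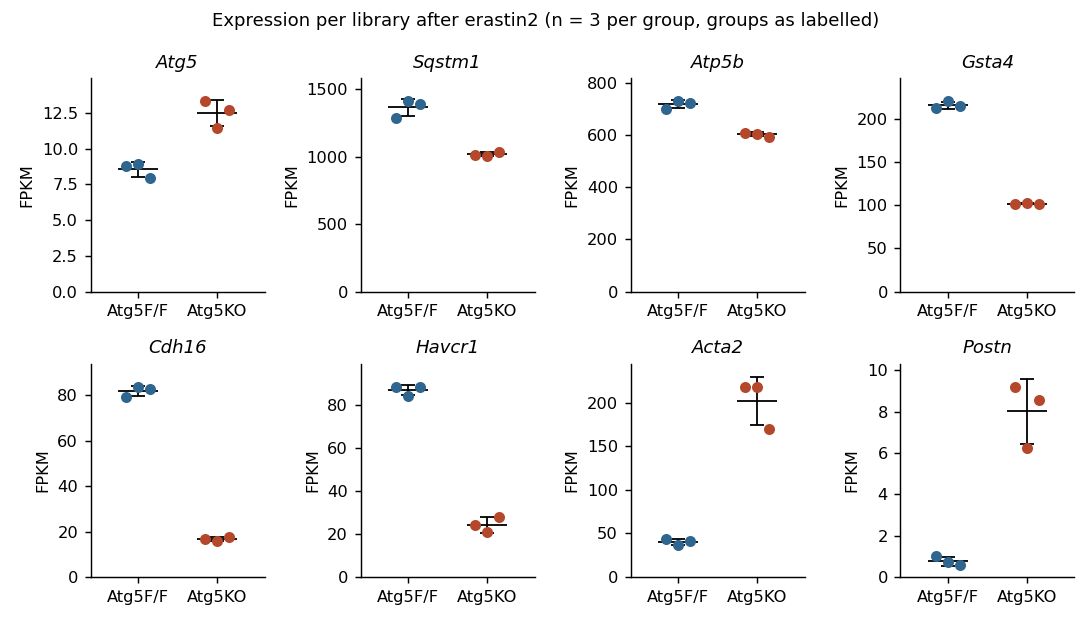
FPKM (y axis) of 8 genes in each library, with 3 F/F-labelled and 3 KO-labelled libraries per panel; points are libraries, and the line and bars are the mean and SD. Atg5, Acta2 and Postn lie higher in all KO-labelled libraries, and Sqstm1, Atp5b, Gsta4, Cdh16 and Havcr1 lie lower.

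Under erastin2, 15 of 19 tested markers of the differentiated proximal tubule were lower in KO-labelled libraries. The camera call of that list was lost with an estimated correlation (adjusted p = 0.19). The largest increases included single genes of contraction, matrix and development, though the lists of matrix and of developmental genes were not called. Of 11559 genes tested, 4530 differed (limma, adjusted p under 0.05), 2457 of them higher and 2073 lower in KO-labelled libraries. Most differences were small: the median absolute log2 fold change of the called genes was 0.27, and 180 also reached an absolute log2 fold change of 1, 79 higher and 101 lower. The 3 values of each group did not overlap for 51.9% of the tested genes, where chance gives 10%. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes.

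The largest increase belonged to Postn (periostin, a matricellular protein), from 0.76 ± 0.21 to 8.01 ± 1.55 FPKM (log2 fold change 2.35, SE 0.14, limma adjusted p = 7.1e-06). Acta2, the smooth muscle actin of contractile cells, went from 40.5 ± 3.4 to 202.2 ± 28 FPKM (2.29, SE 0.099). The secreted glycoprotein gene Fstl1 rose from 5.47 to 29.7 FPKM, Igfbp2 (insulin-like growth factor binding) from 5.24 to 25.8 FPKM, and the proteoglycan gene Sdc3 from 2.15 to 9.67 FPKM. Nrep and the adhesion molecule gene Mcam rose by 1.76 and 1.59 on the log2 scale, and Fam150a, which encodes a receptor tyrosine kinase ligand, by 1.80. Acta1, the skeletal muscle actin, rose by 2.06. Its transcript is closely related to that of Acta2, so reads shared between them leave its value uncertain. Regulators of organ development were among the 12 largest increases: the transcriptional coactivators Eya2 (1.04 to 8.44 FPKM) and Eya4 (1.23 to 6.09 FPKM).

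Among the decreases, Habp2, a secreted serine protease, fell from 12.5 ± 1.0 to 0.71 ± 0.26 FPKM (log2 fold change -2.99). Cdh16, the kidney-specific cadherin, fell from 82.1 ± 2.3 to 16.8 ± 0.87 FPKM (-2.23, SE 0.046). Havcr1, which encodes kidney injury molecule 1, a marker of damaged proximal tubule, fell from 87.2 ± 2.3 to 24.3 ± 3.7 FPKM (-1.81, SE 0.090). Further decreases were those of Cpn1 (-2.17), Guca2b (uroguanylin, -2.09), the protease gene Htra1 (-2.05), Dleu7 (-1.97), Wfdc2 (-1.88), the calcium-binding S100g (-1.76), the EGF receptor ligand gene Areg (-1.73) and G0s2, an inhibitor of triglyceride lipolysis (-1.73).

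The series title states that oxidative phosphorylation was lower after Atg5 knockout, so this list was chosen by the study on these samples and its direction is not independent evidence. A part of the nuclear genes of oxidative phosphorylation was modestly lower in KO-labelled libraries. The list was called by camera with the preset correlation and not by the version with an estimated one. Of 104 tested members of the KEGG list, 47 were lower, 1 was higher and 56 were not called, with a median log2 fold change of -0.18 (camera, adjusted p = 7.5e-09). Adjusted over the list alone, 52 were lower and 2 higher, which for a list chosen on these samples is not independent evidence. The call was lost with an estimated correlation, at an adjusted p = 0.36. The 80 subunits of the respiratory chain and ATP synthase gave 34 lower and 1 higher (39 and 1 adjusted over the list alone), a median of -0.18 and camera adjusted p = 3.8e-08, against an adjusted p = 0.36 with an estimated correlation. The 13 mitochondrially encoded subunits were not analysed here.

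By complex, the decreases were spread over the chain and small in each. Complex I, the NADH dehydrogenase, had 11 of 35 subunits lower and 0 higher (the same counts adjusted over the list alone), with a median of -0.16. The count of lower subunits was 6 without Atg5F/F replicate 3 and 17 without Atg5KO replicate 2. Ndufb9 fell from 218.5 ± 8.6 to 164.2 ± 13 FPKM (-0.41, SE 0.061) and Ndufs8 was lower as well (-0.35). All 4 subunits of complex II, the succinate dehydrogenase, were lower (4 of 4 adjusted over the list alone, median -0.28), from Sdhc at -0.35 to Sdha at -0.16. Complex III had 4 of 9 lower and 0 higher (5 and 0 adjusted over the list alone, median -0.17), with Uqcr10 at -0.38 and Cyc1, cytochrome c1, at -0.29. In complex IV, the cytochrome c oxidase, 6 of 15 were lower and 1 higher (likewise adjusted over the list alone, median -0.19). Its muscle-type subunit Cox6a2 had the largest decrease of the list, from 10.4 ± 1.6 to 3.00 ± 1.1 FPKM (-1.53, SE 0.17), while the testis-type subunit Cox6b2 rose from 3.35 ± 0.14 to 6.89 ± 0.76 FPKM (0.86, SE 0.078). Complex V, the ATP synthase, had 9 of 17 lower and 0 higher (9 and 0 adjusted over the list alone, median -0.15), with Atp5b, its catalytic beta subunit, going from 718.4 ± 15 to 602.8 ± 7.9 FPKM (-0.25). The vacuolar ATPase, the proton pump of lysosomes that the KEGG list also holds, had 8 of 17 lower and 0 higher (8 and 1 adjusted over the list alone, median -0.18), with Atp6ap1 at -0.31. Camera adjusted p-values were 1.7e-05, 0.0082, 0.022, 0.015, 0.0026 and 0.0096 for complexes I to V and the vacuolar ATPase. With an estimated correlation the adjusted p-values were 0.36, 0.30, 0.36, 0.48, 0.36 and 0.36. Factors that assemble the chain were not called as a list (37 tested, 6 lower, 0 higher, median -0.04, camera adjusted p = 0.085). Adjusted over the list alone, 3 were lower and 0 higher. The count of lower factors was also 3 without Atg5F/F replicate 1, Atg5F/F replicate 2 or Atg5KO replicate 3. Uqcc2 stood at -0.34 and Cox17 at -0.29. Over 17 other settings the list was called in 2 (lowest camera adjusted p = 0.043), with medians from -0.07 to -0.03.

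**Figure D2:**
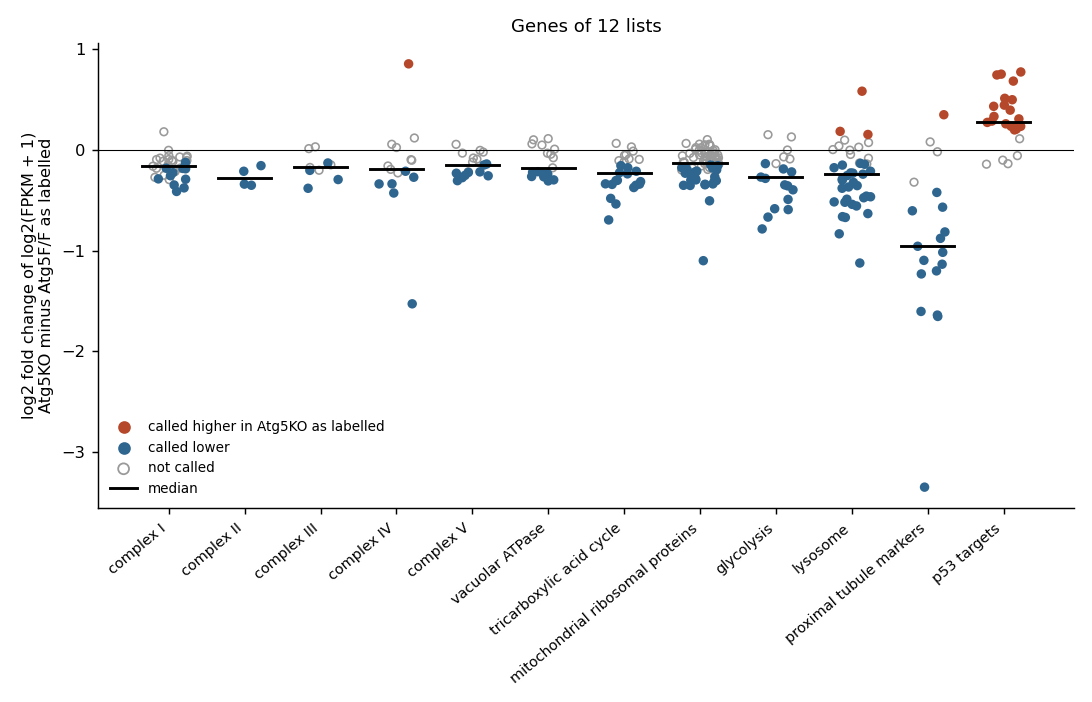
Log2 fold change of each tested gene (y axis, log2(FPKM + 1) scale, KO-labelled minus F/F-labelled libraries, n = 3 per group) in 12 gene lists along the x axis; filled points passed the limma test, open points did not, and black lines are medians. Complexes I to V lie between medians of -0.28 and -0.15, against -0.96 for proximal tubule markers and 0.28 for p53 targets.

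The size of the oxidative phosphorylation change depended on gene length and on a single library. Across genes, which are not independent replicates, each library's deviation from the gene means correlated with gene length at a Spearman rho of -0.20, -0.16 and -0.23 in F/F-labelled and 0.11, 0.04 and 0.34 in KO-labelled replicates 1 to 3, so short transcripts were lower in KO-labelled libraries. With that trend removed in each library, an alternative chosen after seeing the data, the KEGG median was -0.10 (camera adjusted p = 3.1e-04), and complexes III, IV, V and the vacuolar ATPase were no longer called (medians -0.10, -0.10, -0.11 and -0.14, adjusted p = 0.24, 0.30, 0.17 and 0.062). Without Atg5KO replicate 3, the library with the strongest trend, the KEGG median was -0.12, that of the respiratory chain -0.11, and those of complexes I and IV -0.09 and -0.06, and complex III was not called (adjusted p = 0.055). The respiratory chain median was -0.10 with the length trend removed, and complex I stood at -0.09, or at -0.05 with the trend on GC content removed too. Quantile normalization ended the calls of complexes III, IV and V and of the vacuolar ATPase (medians -0.10, -0.12, -0.07 and -0.15, adjusted p = 0.14, 0.084, 0.076 and 0.080) and moved the respiratory chain median to -0.10. The vacuolar ATPase thus lost its call with a median close to the -0.18 it had before.

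Lower transcripts of energy metabolism were not limited to the respiratory chain. In the tricarboxylic acid cycle 16 of 25 genes were lower and 0 higher (18 and 0 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 2.4e-07, adjusted p = 0.19 with an estimated correlation). The lower genes include all 4 complex II subunits, which the respiratory chain list also holds. The largest decreases of the cycle list were outside the chain, in Idh1, the cytosolic isocitrate dehydrogenase, from 26.8 ± 1.1 to 16.2 ± 1.1 FPKM (-0.70), Suclg2 (-0.54) and the mitochondrial Idh2 (-0.48). Glycolysis had 13 of 19 genes lower and 0 higher (15 and 0 adjusted over the list alone, median -0.27, camera adjusted p = 1.9e-06, adjusted p = 0.19 with an estimated correlation). Among them were the monocarboxylate transporter gene Slc16a1 (14.0 to 7.74 FPKM, -0.79), Hk2, a hexokinase (-0.59), and Ldhb (-0.58). Fatty acid oxidation genes had 9 of 22 lower and 2 higher (9 and 2 adjusted over the list alone, median -0.05, camera adjusted p = 0.036, adjusted p = 0.23 with an estimated correlation), led by the thiolase gene Acaa2 (27.1 to 15.1 FPKM, -0.80) and the carnitine palmitoyltransferase gene Cpt1a (-0.29). The fatty acid call was not kept without Atg5F/F replicate 1 (adjusted p = 0.057), with a filter of 5 FPKM (0.054) or with the length trend removed (0.087). Mitochondrial ribosomal proteins had 29 of 78 lower and 0 higher (27 and 0 adjusted over the list alone, median -0.13, camera adjusted p = 2.9e-07, adjusted p = 0.36 with an estimated correlation). Mrps33 stood out among them, falling from 26.6 ± 1.3 to 11.9 ± 1.5 FPKM (-1.10). The median of that list was -0.07 with the length trend removed, at camera adjusted p = 0.0026.

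Regulators of mitochondrial biogenesis went both ways and were not called as a list (18 tested, 1 higher and 5 lower, the same adjusted over the list alone, median -0.05, camera adjusted p = 0.25). Ppargc1a, the coactivator PGC-1alpha, rose from 4.22 ± 0.46 to 6.34 ± 0.30 FPKM (0.49), whereas the nuclear receptor genes Esrrb (-0.62), Ppara (-0.48) and Esrrg (-0.44) fell from low levels. The list median was -0.03 without Atg5KO replicate 3. Mitochondrial dynamics and mitophagy genes had 3 of 17 higher and 3 lower (5 and 4 adjusted over the list alone, median 0.03, camera adjusted p = 0.87). The mitophagy kinase gene Pink1 (0.29) and the mitophagy receptor gene Bnip3l (0.25) were higher. The list median was 0.02, 0.01 and 0.02 without Atg5F/F replicate 2, Atg5F/F replicate 3 and Atg5KO replicate 1, and the count of lower genes was 1 without Atg5KO replicate 3 or without any single F/F-labelled library. Iron-sulphur cluster and haem synthesis had 8 of 25 lower and 2 higher (the same adjusted over the list alone, median -0.12, camera adjusted p = 0.012, adjusted p = 0.36 with an estimated correlation), led by Fdxr (-0.53) and the mitochondrial iron importer gene Slc25a37 (-0.41). That call was lost with the length trend removed (adjusted p = 0.082), and the median was -0.07 without Atg5KO replicate 3. Mitochondrial proteases and chaperones of the mitochondrial unfolded protein response had 10 of 15 lower and 0 higher (10 and 0 adjusted over the list alone, median -0.21, camera adjusted p = 1.7e-05, adjusted p = 0.19 with an estimated correlation), among them Clpp (-0.47), Htra2 (-0.46) and Lonp1 (-0.43). Peroxisomal genes were not called (33 tested, 3 higher and 6 lower, the same adjusted over the list alone, median -0.04, camera adjusted p = 0.19). Pex10 stood at -0.56, and the list median was -0.02 without Atg5KO replicate 1. Over 17 other settings the list was called in 1 (camera adjusted p = 0.048). Cytosolic ribosomal proteins had 21 of 78 lower and 2 higher (19 and 1 adjusted over the list alone, median -0.11, camera adjusted p = 2.2e-04, adjusted p = 0.48 with an estimated correlation), with Rpl12 at -0.61 and Rpl36 at -0.53. The count of lower genes was 10 without Atg5F/F replicate 1 and 9 without Atg5F/F replicate 3. Their call was lost under quantile normalization (adjusted p = 0.080) and with the length trend removed (median -0.03, adjusted p = 0.35). With the trend on GC content removed as well the median was 0.01, and without Atg5KO replicate 3 it was -0.06.

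Lysosomal genes were mostly lower, while genes of autophagosome formation were not called as a list. Of 38 core autophagy genes, 12 were higher and 5 lower (the same adjusted over the list alone), with a median of 0.07 (camera adjusted p = 0.21). The count of lower genes was 1 without Atg5F/F replicate 1 or Atg5F/F replicate 3, 2 without Atg5KO replicate 1, and 3 without Atg5F/F replicate 2 or Atg5KO replicate 2. Besides Atg5, the higher genes included Wipi1, a phosphoinositide-binding protein of the early autophagosome (14.2 ± 0.42 to 20.9 ± 0.83 FPKM, 0.53), Rb1cc1, the FIP200 subunit of the initiating kinase complex (0.45), and its kinase gene Ulk2 (0.33). Cargo receptors were not called either (15 tested, 6 higher and 2 lower, the same adjusted over the list alone, median 0.05, camera adjusted p = 0.37). Their most abundant named member, Sqstm1, which encodes the receptor p62, fell from 1365 ± 65 to 1018 ± 17 FPKM (-0.42, SE 0.061, limma adjusted p = 9.0e-04), whereas Calcoco1 (0.38) and Sec62 (0.26) rose. The median of the receptors was 0.08 without Atg5F/F replicate 1. Lysosomal genes had 28 of 41 lower and 3 higher (30 and 3 adjusted over the list alone), with a median of -0.24 (camera adjusted p = 7.5e-09, adjusted p = 0.19 with an estimated correlation). Examples were the proteases Ctsz, cathepsin Z (153.7 ± 6.0 to 70.0 ± 4.0 FPKM, -1.12), and Lgmn, legumain (178.0 to 99.4 FPKM, -0.83), the sphingolipid activator precursor gene Psap (458.2 to 287.5 FPKM, -0.67) and Hexa (-0.66).

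Ferroptosis regulators, NRF2 targets and enzymes of glutathione and thioredoxin were more often lower than higher in KO-labelled libraries. Ferroptosis regulators had 22 of 40 lower and 4 higher (23 and 5 adjusted over the list alone), a median of -0.16 and camera adjusted p = 1.0e-04, against an adjusted p = 0.19 with an estimated correlation. The list mixes genes that promote and genes that oppose ferroptosis, so its direction does not read as more or less ferroptosis. Without Atg5F/F replicate 3 its count of lower genes was 13. Hmox1, the haem oxygenase, fell from 410.4 ± 17 to 249.1 ± 9.3 FPKM (-0.72), Por, an oxidoreductase that feeds lipid peroxidation, from 59.7 to 36.4 FPKM (-0.70), and the metal importer gene Slc39a14 from 32.6 to 22.6 FPKM (-0.51). The lipoxygenase gene Alox5 rose from 0.46 to 1.30 FPKM (0.66). Named after its value was seen, Slc7a11, the system xc- subunit that erastin2 blocks, was lower by a small amount (-0.16), as was Gpx4, the peroxidase that detoxifies lipid hydroperoxides (-0.24). NRF2 targets had 23 of 38 lower and 4 higher (24 and 4 adjusted over the list alone, median -0.30, camera adjusted p = 5.0e-08, adjusted p = 0.19 with an estimated correlation). The glutathione transferases Gsta2 (-1.34), Gsta1 (85.3 to 35.5 FPKM, -1.24) and Gsta4 (216.2 ± 4.0 to 101.9 ± 0.39 FPKM, -1.08) led the decreases, with the export pump gene Abcc2 (-1.11). The NRF2 median was -0.20 under quantile normalization. Gsta1 and Gsta2 are near-identical neighbours, so the split of reads between them is uncertain. Glutathione and thioredoxin enzymes had 15 of 28 lower and 5 higher (the same adjusted over the list alone, median -0.20, camera adjusted p = 0.0013, adjusted p = 0.27 with an estimated correlation). Sod3, the extracellular superoxide dismutase, fell from 3.18 to 0.48 FPKM (-1.51), and Ggt1, the brush border enzyme that degrades glutathione, from 126.5 ± 10 to 54.4 ± 3.5 FPKM (-1.20). In the other direction, Gclc, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, rose from 271.4 ± 11 to 428.7 ± 17 FPKM (0.66, SE 0.050), and the thioredoxin inhibitor gene Txnip from 90.7 to 162.7 FPKM (0.83).

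Targets of ATF4 and chaperones of the endoplasmic reticulum were lower with the preset correlation, and cytosolic heat shock genes were not. ATF4 and integrated stress response targets had 22 of 44 lower and 2 higher (24 and 4 adjusted over the list alone, median -0.13, camera adjusted p = 2.6e-06, adjusted p = 0.36 with an estimated correlation). The cationic amino acid transporter gene Slc7a3 fell from 52.2 ± 3.0 to 20.4 ± 0.57 FPKM (-1.31), Stc2 from 87.6 to 45.1 FPKM (-0.93), and the hormone gene Fgf21 from 1.92 to 0.74 FPKM (-0.74). Endoplasmic reticulum chaperones and unfolded protein response genes had 15 of 27 lower and 2 higher (15 and 3 adjusted over the list alone, median -0.17, camera adjusted p = 2.3e-04, adjusted p = 0.19 with an estimated correlation), led by Calr, calreticulin (408.2 ± 4.6 to 209.0 ± 6.5 FPKM, -0.96), Hsp90b1 (-0.64) and Hspa5, the chaperone BiP (366.1 to 242.6 FPKM, -0.59). Quantile normalization moved the medians of the ATF4 and endoplasmic reticulum lists to -0.06 and -0.10 without ending either call. Hypoxia targets had 10 of 18 lower and 3 higher (the same adjusted over the list alone, median -0.16, camera adjusted p = 0.012, adjusted p = 0.27 with an estimated correlation), among them the carbonic anhydrase gene Car12 (-1.12), Ndrg1 (-0.89) and Adm, adrenomedullin (-0.84). With a filter of 5 FPKM the hypoxia list had an adjusted p of 0.054, and without a filter its median was -0.02. Cytosolic heat shock genes split 6 higher to 6 lower of 21 (6 and 7 adjusted over the list alone, median 0.00, camera adjusted p = 0.99). Their median and mean were positive and the camera direction was down. Hspb1 rose (0.45) and Hspb8 fell (-0.52).

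Targets of p53, apoptosis regulators and inflammatory genes went the other way. Targets of p53 had 19 of 24 higher and 0 lower (20 and 1 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 8.5e-07, adjusted p = 0.21 with an estimated correlation). The desmosomal effector gene Perp rose from 92.1 ± 4.6 to 158.3 ± 5.1 FPKM (0.78), Pmaip1, the BH3-only protein NOXA, from 100.4 to 169.1 FPKM (0.75), and the death receptor gene Fas from 2.37 to 4.65 FPKM (0.75). Cdkn1a, named after its value was seen, encodes the p53-induced cell cycle inhibitor p21 and did not pass the test (-0.14). Apoptosis regulators had 17 of 30 higher and 0 lower (the same adjusted over the list alone, median 0.18, camera adjusted p = 7.3e-04, adjusted p = 0.19 with an estimated correlation). They held both the executioner caspase gene Casp6 (0.42) and Birc3, an inhibitor of apoptosis (0.43). NF-kB and inflammatory genes had 16 of 22 higher and 1 lower (the same adjusted over the list alone, median 0.28, camera adjusted p = 1.8e-04, adjusted p = 0.19 with an estimated correlation). The chemokine gene Ccl2 rose from 0.42 to 2.23 FPKM (1.17), Tnfaip3, the NF-kB inhibitor A20, from 9.19 ± 1.0 to 18.2 ± 1.3 FPKM (0.92), Cxcl10 from 0.33 to 1.44 FPKM (0.88) and the adhesion molecule gene Vcam1 from 0.57 to 1.87 FPKM (0.85). Without the low-value filter, which added 14 members, the median of that list was 0.07. Interferon-stimulated genes had 11 of 17 higher and 2 lower (12 and 2 adjusted over the list alone, median 0.26, camera adjusted p = 0.0042, adjusted p = 0.36 with an estimated correlation), with the peptide transporter gene Tap1 at 0.45, Gbp2 at 0.40 and Irf1 at 0.39, but Isg20 at -0.40. Their median was 0.17 without the filter. Class I antigen presentation was not called (9 tested, 4 higher and 1 lower, the same adjusted over the list alone, median 0.09, camera adjusted p = 0.23), with Tapbp at 0.39 and H2-T23 at 0.32. Its median was 0.14 without Atg5F/F replicate 2 and 0.04 without Atg5F/F replicate 3. Necroptosis and pyroptosis genes were not called (5 tested, 1 higher and 3 lower, the same adjusted over the list alone, median -0.24, camera adjusted p = 0.23). Ripk3, the necroptosis kinase, fell from 4.98 ± 1.0 to 2.74 ± 0.33 FPKM (-0.66), and Ripk1 rose (0.29). The list median was 0.00 without the filter (14 tested) and -0.08 with a filter of 5 FPKM (3 tested), so the list had no stable direction.

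With the expression filter, markers of the differentiated proximal tubule showed the largest median decrease of any list. Of 19 tested, 15 were lower and 1 higher (16 and 1 adjusted over the list alone), with a median of -0.96 (camera adjusted p = 7.5e-09, adjusted p = 0.19 with an estimated correlation). These included the fatty acid transporter gene Slc27a2 (8.96 ± 2.1 to 2.16 ± 0.59 FPKM, -1.65), Keg1 (5.20 to 0.96 FPKM, -1.64) and Fxyd2, a subunit of the sodium pump (6.42 to 1.47 FPKM, -1.60). Of the 45 listed markers 26 did not reach the expression filter, and without the filter the median was -0.21 with 20 lower and 0 higher of 42. The ranking was then lost: all 25 tricarboxylic acid cycle genes passed the filter, with a median of -0.23. Injury and dedifferentiation markers were not called (30 tested, 11 higher and 7 lower; 13 and 9 adjusted over the list alone, median 0.09, camera adjusted p = 0.51). Havcr1 and the cornified envelope gene Sprr1a (31.0 ± 0.29 to 9.99 ± 2.8 FPKM, -1.57) fell, and the simple epithelial keratin gene Krt18 rose from 85.5 ± 6.2 to 184.3 ± 14 FPKM (1.10).

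Transcripts assigned to other cell types changed only in part. Fibroblast and mesangial markers had 4 of 6 tested genes higher and 1 lower (the same adjusted over the list alone, median 1.07, camera adjusted p = 0.010, adjusted p = 0.19 with an estimated correlation), namely Postn, Acta2, Tagln (28.6 ± 0.61 to 64.9 ± 5.3 FPKM, 1.15) and Fn1, fibronectin (237.4 ± 13 to 472.2 ± 32 FPKM, 0.99). Those 4 encode matrix or contractile proteins that are not specific to fibroblasts. The other 18 listed markers, among them the collagen genes Col1a1 (0.064 and 0.18 FPKM) and Col1a2 (0.025 and 0.0037 FPKM) in F/F-labelled and KO-labelled libraries, did not reach the filter. Without the filter the list had a median of 0.02 and was not called (adjusted p = 0.19). Podocyte markers (6 tested, 1 higher and 2 lower, camera adjusted p = 0.67), endothelial markers (3 tested, 0 higher and 1 lower, 0.69) and macrophage and leukocyte markers (3 tested, 0 called, 0.49) were not called as lists, and their counts adjusted over the list alone were unchanged. In the podocyte list Cdkn1c was lower (-0.87) and Podxl higher (0.58); the endothelial receptor gene Kdr was lower (9.06 to 5.53 FPKM, -0.63); and Cd68 was at 5.01 and 4.19 FPKM (-0.21, limma adjusted p = 0.062). Only 2 of 22 markers of other nephron segments passed the filter, Wnk4 and Trpm6, both lower by 0.52 on the log2 scale, so that list was not tested.

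Matrix and TGF-beta target genes went both ways and were not called (28 tested, 11 higher and 7 lower, 11 and 8 adjusted over the list alone, median 0.10, camera adjusted p = 0.23). Col12a1 rose from 5.50 ± 0.42 to 16.1 ± 0.22 FPKM, Lox, the collagen cross-linking enzyme, from 23.7 ± 1.4 to 61.0 ± 2.8 FPKM (1.33), and Thbs1, already at 726.8 FPKM, to 1083 FPKM (0.57). The matrix median was 0.05 without the filter, 0.03 with the length trend removed and 0.00 with the trend on GC content removed too. Cell cycle genes were not called (19 tested, 6 higher and 0 lower, the same adjusted over the list alone, median 0.13, camera adjusted p = 0.24), with the DNA replication genes Rrm1 (0.48), Gins2 (0.45) and Mcm7 (0.33) among the higher ones. Their median was 0.07, 0.06 and 0.05 without Atg5F/F replicate 1, Atg5F/F replicate 3 and Atg5KO replicate 3, and the count of higher genes was 3 without Atg5F/F replicate 1, Atg5F/F replicate 3 or Atg5KO replicate 1. Immediate early genes were not called (18 tested, 8 higher and 2 lower, 9 and 2 adjusted over the list alone, median 0.09, camera adjusted p = 0.19), with Klf2 (0.69) and Fos (0.54) higher and Fosl1 (-0.82) lower. Their median was 0.14 without Atg5F/F replicate 1 and 0.05 without Atg5F/F replicate 2. Cholesterol genes were not called (24 tested, 8 higher and 2 lower, the same adjusted over the list alone, median 0.09, camera adjusted p = 0.46), with Stard4 at 0.44, Insig1 at 0.37 and Sqle at -0.26. The count of higher cholesterol genes was 5 without Atg5F/F replicate 3 or Atg5KO replicate 1, and their median was 0.06 without Atg5KO replicate 3.

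**Figure D3:**
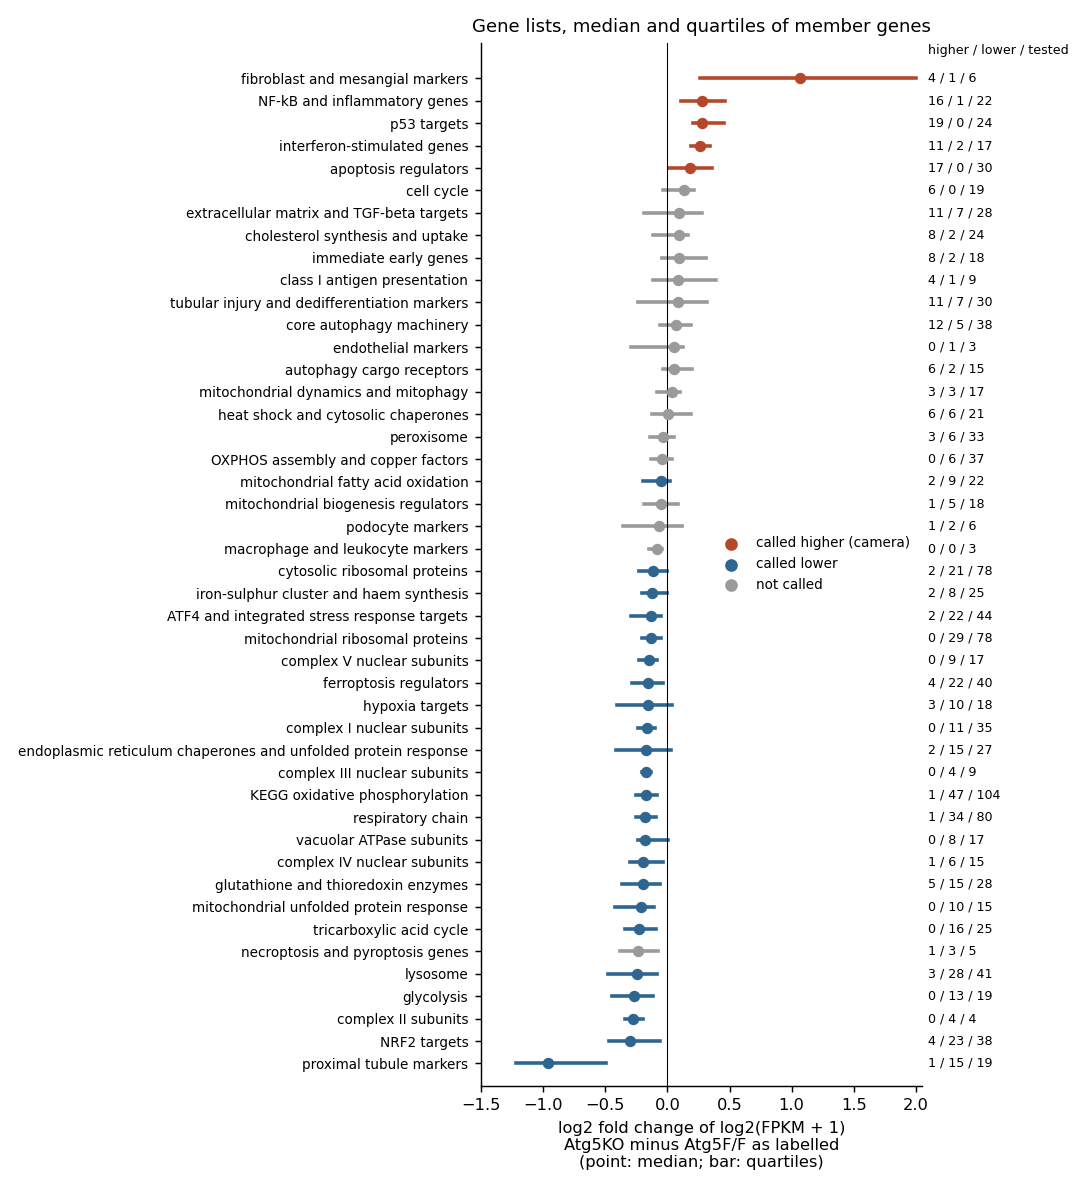
Median (point) and quartiles (bar) of the log2 fold change of member genes (x axis, log2(FPKM + 1) scale, KO-labelled minus F/F-labelled libraries) for each tested list (y axis), coloured by the camera call with a preset correlation and with the counts of genes higher, lower and tested at the right. Proximal tubule markers lie lowest at -0.96 and fibroblast and mesangial markers highest at 1.07; no list was called with an estimated correlation.

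With the preset correlation, camera called 26 of the 43 fixed lists that could be tested, 5 higher and 21 lower. With a correlation estimated from the 6 libraries it called 0, with 11 at an unadjusted p under 0.05, and fry called 34. Several genes sit in more than 1 list, so the lists are not independent. An FDR under 0.05 was given in the authors' deposited table to 5375 genes, 2591 higher and 2784 lower in Atg5KO; 4762 of them were among the genes tested here, and 4091 were called in both, all with the same sign.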

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

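The tests on recovered reads and on length or GC trends were chosen after the result was seen; the others were planned. The count of 4530 called genes ran from 3265 (without Atg5F/F replicate 3) to 5582 (adjusted p under 0.10) and stayed within 1.5 times of itself under each of these settings except the fold threshold: with an absolute log2 fold change of at least 1 it was 180 (79 higher, 101 lower). Voom on recovered reads called 5064. Median-ratio scaling and removal of the length trend moved the share called higher from 54.2% to 48.3% and 48.9%, and no setting moved the median of all genes beyond 0.022 in log2. The KEGG oxidative phosphorylation median kept its sign under every refit that could move it (block, robust eBayes and variance trend cannot), from -0.20 to -0.10, and ran from -0.205 to -0.115 over the libraries left out in turn. With an estimated correlation its value stayed at -0.176 (adjusted p = 0.36) and the fixed lists called fell from 26 to 0. That version of the test rests on 4 residual degrees of freedom. A higher correlation alone does not account for the loss. The mitochondrial unfolded protein response list had an estimated correlation of 0.0125, near the preset 0.01. Its unadjusted camera p still went from 4.5e-06 to 0.011. Fibroblast and mesangial markers had an estimated correlation of -0.026, and their unadjusted camera p went from 0.0053 to 0.046. The cause was not tested further. Lists called numbered 22 under quantile normalization and 19 with the length trend removed. Atg5 was higher by 0.45 to 0.55 under each refit.

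Some list medians changed sign, none of them in a called list except that of cytosolic ribosomal proteins (0.0063 with length and GC trends removed), and the cause was not tested: mitochondrial biogenesis regulators with a filter of 5 FPKM (0.016), mitochondrial dynamics with the length trend (-0.020) or length and GC trends removed (-0.021), cargo receptors with the latter (-0.0029), necroptosis genes (from -0.24 to 0.0026) and endothelial markers (-0.011) without the filter, podocyte markers without Atg5F/F replicate 2 (0.017) or Atg5KO replicate 1 (0.023), macrophage markers without Atg5F/F replicate 3 (9.4e-04) or Atg5KO replicate 3 (0.0055), and heat shock genes in median or camera direction with a replicate block (0.0042), fry (0.0042), quantile normalization (0.069), voom (0.0028), median-ratio scaling (-0.016), length (-0.018) and length and GC (-0.028) removed, and -0.032 to 0.044 over the libraries left out. Cd14 ran from -0.21 to 0.032 over the libraries left out, and was uncalled in each.

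The replicate numbers did not clearly pair the libraries: deviations of same-numbered libraries correlated at 0.16, 0.075 and -0.023. Differently numbered libraries of the 2 groups ran from -0.13 to 0.047. Not every library correlated best with its own number, but the highest values were of same-numbered libraries, so a weak pairing is not excluded. With a replicate block 4668 genes were called. Without the filter on low values 18296 genes were tested and 4266 called.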

Other observations

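The gene families and chromosome windows that come first were chosen after the result was seen. So were the tests of an exchange of labels, of the region around Atg5 and of fibroblasts, and the widening of matched lists for correlation. The other tests were set before their values were computed, but that of epithelial share used the pan-epithelial family, which was chosen afterwards.

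Beyond the fixed lists, most tested contractile and general epithelial genes were higher in KO-labelled libraries and most brush border genes were lower. Camera with the preset correlation called the 5 families of this paragraph (largest adjusted p = 0.0026), and with an estimated correlation it called 0 of them (adjusted p = 0.065 to 0.15). As the families were chosen on these data, those p-values are not independent evidence. Of 15 tested smooth muscle and contractile genes 13 were higher and 0 lower (median log2 fold change 0.82), including Tpm1 (206.9 to 410.8 FPKM), Cald1 (192.1 to 337.9 FPKM) and Myl9 (1.18 to 5.30 FPKM). Of 14 pan-epithelial genes 9 were higher and 1 lower (median 0.42), among them the adhesion gene Epcam (11.5 to 29.4 FPKM), Cdh1, E-cadherin (14.0 to 20.8 FPKM), and the splicing regulator gene Esrp1 (5.09 to 10.1 FPKM). Brush border and microvillus genes had 9 of 11 lower and 1 higher (median -0.72, or -0.42 without the filter, which had left out 7 of 18), with Folh1 going from 25.8 to 8.15 FPKM and Myo7b from 9.32 to 2.69 FPKM, while the peptidase gene Mme rose from 8.18 to 12.6 FPKM. Glutathione S-transferases had 12 of 19 lower and 0 higher (median -0.42), with medians of -0.53 to -0.33 over other settings, though reads may be split wrongly between near-identical copies. Among 11 actin-binding and adhesion targets of YAP and SRF 6 were higher and 1 lower (median 0.22).

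Developmental regulators moved individually rather than as a family: of 19 tested EYA, PAX, IRX and related genes 7 were higher and 5 lower (median 0.05, or 0.13 and 0.10 without Atg5F/F replicates 1 and 3 and 0.25 with a filter of 5 FPKM). Irx1 rose from 4.16 to 12.8 FPKM and Irx2 from 5.92 to 14.0 FPKM beside Eya2 and Eya4, whereas Bmp7 fell from 4.96 to 1.39 FPKM and Osr2 from 7.85 to 4.15 FPKM. Pax8, a general renal epithelial factor, was at 233.6 and 240.9 FPKM and was not called. Of 634 windows of 3 Mb with at least 5 tested genes, 1 held more genes past an absolute log2 fold change of 1 than chance after adjustment: chromosome 9 from 78 to 81 Mb, with 6 of 17 (adjusted p = 8.5e-05). It holds the Gsta cluster, whose members share sequence, and Col12a1, which changed in the other direction.

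The number of called genes was 4530 for the labelled split and at most 0 for the other 9 splits of the 6 libraries (limma; 1 of 10 splits gave as many). With 10 splits no share under 0.05 can be had. Each of the other 9 splits also mixes the 2 groups, which puts the group difference into the spread, so its 0 calls are no measure of chance.

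Higher Atg5 in KO-labelled libraries does not follow its neighbourhood or transcript length. The 7 other tested genes within 1 Mb had a median log2 fold change of -0.067 and at most 0.054, and with the length trend removed Atg5 stayed at 0.497 (limma adjusted p = 5.4e-04). That removal could hardly have moved Atg5: genes of similar length (1545 to 2395 bp) had a median log2 fold change of only -0.020 before it. An exchange of labels between the groups, which would make the libraries with less Atg5 (log2 fold change 0.499) the knockout, cannot be told apart from a knockout that keeps or raises a transcript lacking an exon: no recombinase or reporter gene was found among the symbols, and exon reads were not analysed here. As a hypothesis, loss of autophagy may raise NRF2 targets through p62 binding of KEAP1. In KO-labelled libraries 23 of 38 NRF2 targets were lower and 4 higher (median -0.30), with Gclc at 0.66. Sqstm1 transcripts were lower (-0.42), which does not give the level of p62 protein. These values do not decide on an exchange of labels. Reads over the floxed exon would settle it, and all directions rest on the labels until then.

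Lower oxidative phosphorylation genes may in part follow a shift of short transcripts. The respiratory chain median went from -0.176 to -0.0988 with each library's length trend removed, still below the -0.05 set beforehand as the mark of a length bias, with a camera adjusted p of 0.0017 at the preset correlation but 0.27 with an estimated one. That second criterion was not met before the correction either (0.36), so a length bias cannot be told apart as the whole cause. A shift of all short, highly expressed genes stays open too: the median of -0.176 lay at percentile 0.12 of 10000 lists matched on length and expression (median -0.096), but the study chose the list on these samples, and the matched genes were drawn singly while those of the list correlated at an estimated 0.387. Widened for that correlation, the lower bound of the matched lists was -0.43, below the value of the list, so an effect of genotype was not told apart from either.

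For lower proximal tubule markers with higher contractile genes, the values argue against collagen-rich fibroblasts as the source. Other contractile cell types were not tested. A smaller share of epithelial cells was not excluded, and a shift between epithelial types stays open. Markers of other nephron segments were not higher (without the filter 15 tested, 0 higher and 4 lower, median -0.01, camera adjusted p = 0.040, or 0.24 with an estimated correlation), though most lay near 0 FPKM and other epithelial types were not tested. Abundant fibroblast transcripts (8, with collagens, Dcn and Lum) had a median of 0.0185 FPKM in KO-labelled libraries, the abundant Sparc among them being lower (-0.30), where fibroblasts in the culture would bring them in bulk. A smaller share of epithelial cells would lower the pan-epithelial genes at a fixed level per cell, whereas their median was 0.424. The level per cell was not measured and the family was chosen after the result, so a smaller share is not excluded. The length trend does not carry the pattern, since the proximal tubule median was -0.934 after its removal. A less differentiated, more contractile state of the epithelial cells is a hypothesis. The injury and dedifferentiation markers were not called as a list (camera adjusted p = 0.51). Whether such a state would follow from genotype, time in culture or survival under erastin2 was not tested.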
